A study of Caenorhabditis elegans with 19 samples.

How the data were processed

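Small RNA libraries were made from whole-animal pellets of 3 strains grown at 20 °C on HB101 bacteria. All strains carried the adult-specific col-19::gfp reporter and a lin-31 mutation that keeps alg-1 mutants from bursting through the vulva, and the wild-type control differed only in having normal alg-1. RNA came either from the clarified lysate (total RNA) or from the material that an anti-ALG-1 antibody pulled down. The design text says that replicates are biological. The labels name the library protocol and 2 sequencing instruments, without saying which library ran on which. Per the file headers and the labels, the deposited values are counts: the authors collapsed the reads of each library to distinct sequences and gave the number of reads of each. The reads start at 17 nt, Bowtie is named in the processing notes without a version, and the genome build and the trimming tool are not given in the sources used here. No value in the files was scaled.

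Because the files name no miRNA and no genome was used, strands were recognised by sequence. A list of 109 guide strands was written by hand from general knowledge, with names checked against the gene table (assembly WBcel235, 100 hairpin names found, names only), and 104 were kept, each with at least 500 reads over all libraries and its expected form among the 3 most abundant of its kind. For 72 of them a passenger was chosen from abundant reads, at least 50 in all, that pair with the guide, using counts pooled over all libraries and no comparison of groups. The pool included the mutant libraries. Strands abundant mainly in the mutants could thus enter the list, which can favour the counts of risen passengers and hairpins. A read was assigned by its first 18 bases, with a start shifted by at most 1 nt and a length of at most 30 nt. In duplexes folded with ViennaRNA 2.7.2, 65 of 72 pairs had overhangs of 1 to 3 nt at both ends, and the chosen passenger was the most stable partner for 59 and among the 3 most stable for 70 (median -19.1 kcal/mol). Passengers of near-identical relatives (mir-51 to mir-53, mir-80 to mir-82 and mir-90, mir-46 and mir-47, mir-64 and mir-65, mir-36, mir-37 and mir-42, mir-44 and mir-45) can be exchanged by this method. The lists of strands were completed after the most abundant sequences of the files had been seen. A hairpin's guide is its more abundant strand over all wild-type libraries, each weighted equally. From the immunoprecipitations alone 1 hairpin (mir-788) and from L2 animals alone 1 (mir-243) would have had the other strand as guide. The let-7 guide was TGAGGTAGTAGGTTGTATAGTT with passenger CTATGCAATTTTCTACCTTACC, and the lin-4 guide TCCCTGAGACCTCAAGTGTGA with passenger ACACCTGGGCTCTCCGGGTACC. Ribosomal and transfer RNA fragments, 5p and 3p arm sets, and the miRNAs mir-266, mir-269, mir-273, mir-797 and mir-1018 were not analysed here, and of the mirtrons only mir-62 was measured.

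Counts were read into R 4.3.3. The groups and comparisons, the tests, the lists and the rule for naming strands were fixed before the data were examined. Each library set was fitted once in edgeR 4.0.16 (TMM factors over all strands, quasi-likelihood F test) with a mean for each genotype, and the contrasts were each allele against wild type, the mean of both alleles against wild type and ma202 against ma192. The 14 mixed-stage libraries were fitted together for immunoprecipitation against total RNA and its interaction with genotype. The lone ma192 L2 library was assumed to vary like the other groups, and no call was made from it alone. Adjusted p values are Benjamini-Hochberg, over all strands tested, at 0.05. The standard error of an edgeR log2 change was taken as its size over the square root of F. The passenger-to-guide ratio, log2 of passenger plus 0.5 over guide plus 0.5, was tested in limma 3.58.1 (robust moderation) for hairpins with a mean of at least 20 reads. Sets were tested with camera at a preset correlation of 0.01 and at an estimated one. Shares per library were compared with 2-sided exact permutation tests. Of 20 lists of miRNA families and of stage or tissue markers, 19 had 2 or more measured guides. The lists overlap: let-7, miR-48 and miR-84 are in the let-7 family and in marker lists, and whole animals express all lists together. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used for counting, permutations and plots.

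Strands were named by a fixed rule: the 10 largest rises and 10 largest falls past the threshold with every mutant library on 1 side of every wild-type library, the 10 hairpins with the largest ratio change, up to 4 members of each list with the highest mean level, switching hairpins, and always let-7, lin-4, mir-58, mir-71, mir-1 and mir-35. A switch is a passenger share over 50% in every mutant and under 50% in every wild-type library. A strand absent from a group was set against a floor of 3 counts over the group. Intervals are Wilson intervals at 95%, and they and the floors cover counting error only, because the reads carry no molecular identifiers.

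Replicate numbers were checked as pairs. After group means were removed, libraries of the same number were positively correlated in 6 of 6 pairs of mixed-stage total RNA (r 0.107 to 0.568), 6 of 6 of the immunoprecipitations (0.112 to 0.614) and 7 of 7 between total RNA and immunoprecipitation (0.196 to 0.532). With 2 libraries per mutant group the residuals mirror each other, so some of these values repeat (0.568, 0.614, 0.196 and 0.272). The tallies therefore overstate the evidence. Pairs of different numbers reached 0.238 in total RNA and 0.194 bound, above the lowest same-number values, and -0.0258 between the 2 kinds of RNA. A fit with replicate number as a block was set beside the results. Wild-type replicate 3 has no mutant partner, and L2 animals have only 2 pairs. The share of reads with an undetermined base also followed the numbers.

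Alternatives were DESeq2 size factors, library size alone, TMM from guides alone, scaling to all reads of the file, the DESeq2 1.42.0 Wald test, no filter on low counts, reads with the exact 5′ end, an offset of 5, hairpins with a mean of 100 reads, guides holding at least 90% in wild type, and each library left out. limma without robust moderation was added after the data were seen. Methods were tested on simulated data with 40 changed strands or 20 changed hairpins. The 40 strands rose and fell in turn, unlike the measured passengers, most of which rose. These simulated data could therefore not show guides called lower through scaling. In mixed-stage total RNA edgeR recovered 3 of 14 changes of 2-fold, 13 of 13 of 4-fold and 13 of 13 of 16-fold, with 0 of 136 unchanged strands called. In the immunoprecipitations it recovered 6 of 14, 12 of 13 and 13 of 13 with 2 of 135 called. In L2 animals it recovered 0 at each size, so an absent call there says little. The ratio test recovered 2 of 7, 5 of 7 and 6 of 6 in total RNA, 2 of 7, 2 of 7 and 6 of 6 bound, and 0 in L2 animals, and 1 unchanged hairpin was called in each mixed-stage set. The interaction recovered 2 of 14, 8 of 13 and 13 of 13 with 3 of 136 called, and its ratio test 0 of 7, 1 of 7 and 4 of 6.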

Results

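Small RNAs were sequenced from whole Caenorhabditis elegans carrying 1 of 2 antimorphic alleles of alg-1, ma192 or ma202, and from wild-type controls. ALG-1 is an Argonaute protein that loads 1 strand of each microRNA (miRNA) duplex, the guide, while the other strand, the passenger, is normally released and degraded. Passenger strands carry an asterisk here, as in let-7*. An antimorphic allele makes a protein that interferes with the process in which the normal protein acts. Total RNA of mixed-stage animals came from 3 wild-type, 2 ma192 and 2 ma202 libraries, RNA bound to ALG-1 in mixed-stage animals (anti-ALG-1 immunoprecipitation) from another 3, 2 and 2, and total RNA of animals in the L2 larval stage from 2, 1 and 2. The libraries held 3351934 to 8427601 reads in mixed-stage total RNA, 3110978 to 11858271 in the immunoprecipitations and 4294546 to 27367557 in L2 animals. Reads of the 176 strands measured numbered 1145783 to 4546038, 2322344 to 6005186 and 2383738 to 17103395 per library in these sets.

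The first question was whether the antimorphic proteins alter which strand of a miRNA duplex is kept. Passenger strands made up 0.559% ± 0.0637 (SD, n = 3) of guide and passenger reads in wild-type mixed-stage total RNA. They made up 9.93% ± 0.281 (SD, n = 2) in ma192 and 15.5% ± 0.369 (SD, n = 2) in ma202, a 22.8-fold higher mean over the 4 mutant libraries (12.7% ± 3.25, SD, n = 4). Among ALG-1-bound reads the passenger share was 0.299% ± 0.0154 (SD, n = 3) in wild type and 8.04% ± 4.95 (SD, n = 4) in the mutants, 26.9-fold higher. In L2 animals it was 1.16% ± 0.194 (SD, n = 2) in wild type and 27.9% ± 6.21 (SD, n = 3) in the mutants, 24.1-fold higher. The lone ma192 L2 library stood at 20.7% (Wilson 95% confidence interval 20.7 to 20.7%) and the ma202 L2 libraries at 31.5% ± 0.222 (SD, n = 2). Every mutant library lay above every wild-type library in each of the 3 sets. In mixed-stage and L2 total RNA the gap was wider than the spread between replicates. In the immunoprecipitations it was not, with 3.02% in the lowest mutant and 0.309% in the highest wild-type library, beside the mutant SD of 4.95. A 2-sided exact permutation test of the difference gave p = 0.0286 in mixed-stage total RNA, the smallest of its 35 splits, p = 0.0571 in the immunoprecipitations (0.0286 being the smallest there too) and p = 0.1 in L2 animals, where 10 splits allow nothing smaller. Permuted within mixed-stage and L2 total RNA together, the exact p was 0.00286, the smallest that 350 regroupings allow. The immunoprecipitations of replicate 1 held passenger shares of 8.89% (ma192) and 14.5% (ma202), and those of replicate 2 held 3.02% and 5.71%.

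**Figure D1:**
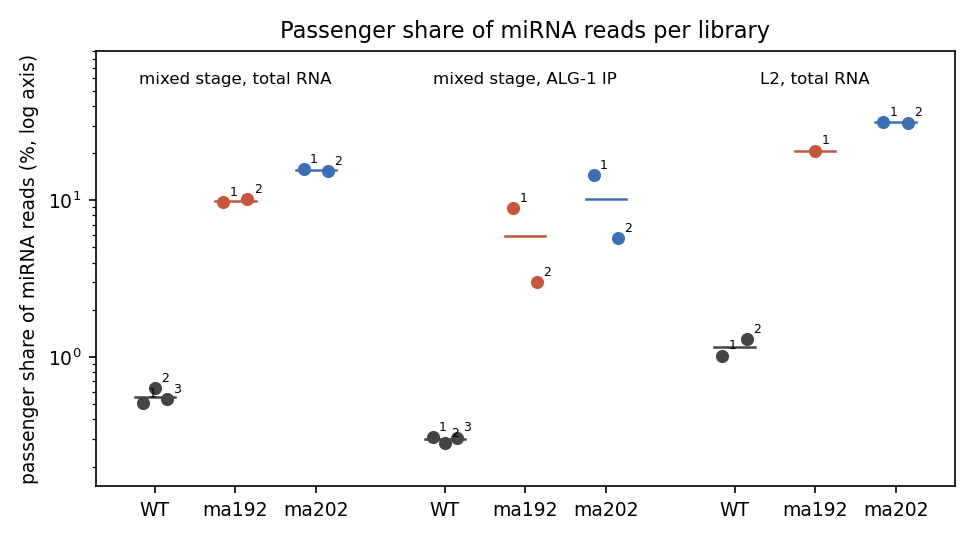
Passenger strands as a percentage of guide and passenger reads (vertical axis, log scale) in each library of the 3 sets, by genotype, with a numbered point for each library and a short line at each group mean. Wild-type libraries of mixed-stage total RNA lay between 0.507% and 0.630% and mutant libraries between 9.73% and 15.8%.

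Read hairpin by hairpin, the shift in mixed-stage total RNA reached miRNAs of many families. The passenger-to-guide ratio of lin-4, a miRNA that times larval development, rose 428-fold in the mutants (log2 8.74 ± 0.63, standard error; limma, adjusted p = 6.13e-08; n = 4 and 3 here and below). Its passenger lin-4* held 0.0376% ± 0.0262 (SD) of the hairpin's reads in wild type, 31.0% ± 2.98 in ma192 and 4.50% ± 2.42 in ma202. The let-7 passenger, from the hairpin of another developmental timer, went from 0.0668% ± 0.0475 to 8.37% ± 0.269 in ma192 and 6.51% ± 0.390 in ma202, and the ratio rose by 7.17 ± 0.64. The 10 largest rises were those of lin-4, mir-64 (366-fold), mir-81 (361-fold), mir-235 (266-fold), mir-86 (230-fold), mir-52 (187-fold), mir-793, mir-67, mir-56 and let-7 (144-fold). The ratio also rose for the muscle miRNA mir-1, by 6.65 on the log2 scale from 0.214% passenger in wild type, and for the abundant mir-58 (0.298% to 8.40% ± 3.14) and mir-71 (0.919% to 32.4% ± 11.4). The embryonic mir-35 rose by 3.92 on the log2 scale. In limma 59 of 72 hairpins passed the threshold upward and 1 downward, with a median change of 4.68 (25.6-fold), 71 of 72 changes above 0, and 56 hairpins higher in every mutant library than in any wild-type library, which chance gives in 2.86% of hairpins each way. The exception was mir-62, whose miRNA is cut from a spliced intron (a mirtron): its ratio fell by 1.82 ± 0.66 (adjusted p = 0.0181), from 19.1% ± 6.66 to 7.15% ± 5.62 passenger, with overlapping libraries. The ratio is taken within a hairpin and library, so the scaling of libraries does not enter it.

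In 3 hairpins of mixed-stage total RNA the former passenger became the more abundant strand in all 4 mutant libraries and was below 50% in all 3 wild-type libraries. The mir-2 passenger went from 7.39% ± 2.87 (SD, n = 3) to 75.7% ± 2.71 in ma192 and 96.0% ± 2.04 in ma202 (n = 2 each). That of mir-87 went from 9.41% ± 3.39 to 65.2% ± 20.1 and 91.7% ± 6.57, and that of mir-235 from 1.86% ± 1.72 to 74.1% ± 17.9 over both alleles (SD, n = 4). By allele, 4 hairpins switched in ma192 (mir-85 in addition) and 9 in ma202 (in addition mir-44/mir-45, mir-54, mir-86, mir-90, mir-244 and mir-788, but not mir-85). Among ALG-1-bound reads 0 hairpins switched in both alleles and 5 in ma202 (mir-2, mir-86, mir-87, mir-241, mir-244), with 0 in ma192. In L2 animals mir-47 and mir-75 switched in both alleles. Switches were counted without a test.

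Scored strand by strand in mixed-stage total RNA, the largest rises were all passengers and the largest falls all guides. The passenger of mir-85 rose 70.5-fold (log2 6.14 ± 0.69, adjusted p = 9.67e-08, edgeR), miR-64* 66.9-fold, miR-52* 63.8-fold, miR-67* 57.8-fold, lin-4* 57.0-fold (5.83 ± 0.67), miR-43* 55.2-fold, let-7* 51.5-fold (5.69 ± 0.61), miR-235* 51.2-fold, miR-793* 49.9-fold and miR-81* 49.3-fold. Among guides miR-50 fell by 4.18 ± 0.47 (18.1-fold, adjusted p = 9.67e-08), miR-785 by 4.17, the let-7 relative miR-241 by 3.35 ± 0.55, the muscle miRNA miR-1 by 3.17 ± 0.36 (8.99-fold), and miR-359, miR-784, miR-248, miR-56, miR-795 and miR-792 by 3.12 to 2.80 on the log2 scale. lin-4 fell 6.74-fold (-2.75 ± 0.41, adjusted p = 2.91e-06), miR-71 4.34-fold, let-7 3.45-fold (-1.79 ± 0.46, adjusted p = 0.00168) and miR-58 2.15-fold, while miR-35 was not past the threshold (-0.63 ± 0.47, adjusted p = 0.231). Of 104 guides 2 rose and 65 fell, and of 72 passengers 61 rose and 2 fell (unadjusted, 65 strands of 176 higher and 70 lower). In every mutant library against every wild-type library, 58 strands lay higher and 47 lower, which chance gives for 2.86% of strands each way. The fall of guides depended on the scaling of libraries. Scaled over all strands (TMM) the median guide change was -1.35, scaled by library size -0.23 (11 guides higher, 20 lower), by all reads -0.77 (3 and 35), by DESeq2 size factors -1.38 (3 and 66), and by TMM from guides alone 0.03 (18 and 17). Under all 5 scalings the guides lin-4, miR-1, miR-50, miR-54, miR-56, miR-64, miR-65, miR-73, miR-81, miR-82, miR-241, miR-248, miR-359, miR-784, miR-785, miR-792 and miR-795 (17 in all) fell, miR-36 and miR-41 rose, and 61 passengers rose; lin-4 then ranged from -2.79 to -1.32, miR-1 from -3.24 to -1.77 and miR-36 from 1.76 to 3.11. The let-7 fall passed the threshold in 2 of the 5.

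**Figure D2:**
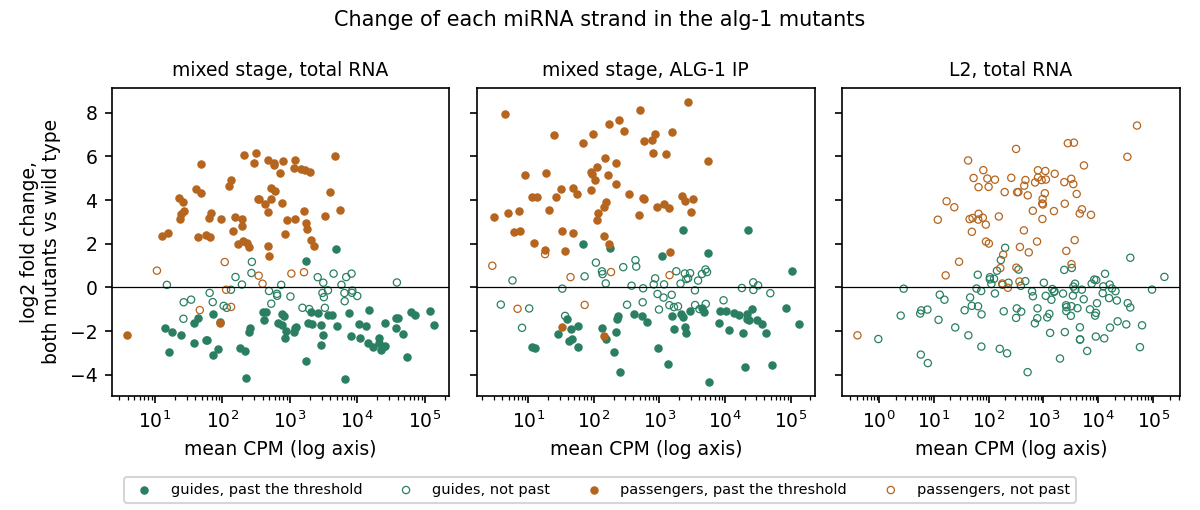
Log2 change of each strand in the mutants against wild type (vertical axis) over its mean count scaled to library size (CPM, horizontal axis, log scale), with a point for each guide (green) or passenger (orange), filled where past the threshold, and a panel for each library set. Passengers centre on 3.25, 4.07 and 3.83 and guides on -1.35, -0.96 and -0.72 in mixed-stage total RNA, immunoprecipitations and L2 animals, and with TMM from guides alone the guide medians are 0.03, -0.24 and 0.06.

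In mixed-stage total RNA most measured guides of the let-7, mir-51, mir-58, mir-64 and mir-72 families fell strand by strand, though no family passed a test of the list as a whole. In the let-7 family 0 of 7 rose, 6 fell and 1 was not past the threshold, miR-48 (0.22); miR-84 fell by 1.17. In the mir-51 family all 6 guides fell (median -1.56), among them miR-52 by 1.27, miR-55 by 1.85 and miR-54 by 2.74. In the mir-58 family 4 of 5 fell, with miR-80 by 1.72, miR-81 by 2.53 and miR-82 by 2.32, and in the mir-64 family 4 of 5, with miR-66 by 1.42 and miR-65 by 2.67 but not miR-229 (0.12). All 3 guides of the mir-72 group fell, miR-72 by 1.14, miR-74 by 1.28 and miR-73 by 2.65, and 7 of the 9 broadly expressed miRNAs did, miR-77 by 1.38. With TMM from guides alone these counts were 1 higher and 2 lower (let-7 family), 0 and 2 (mir-51), 0 and 2 (mir-58), 0 and 2 (mir-64), 0 and 1 (mir-72) and 0 and 1 (broadly expressed), with medians of -0.45, -0.17, -0.30, -0.30, 0.06 and 0.02. In the embryonic mir-35 family 2 of 8 rose and 0 fell (median -0.26, mean 0.10, camera direction down), with 3 rising under TMM from guides alone (median 1.08), and miR-40, miR-42 and miR-38 were not past the threshold. Single members fell in the lin-4 (1 of 2, miR-237 not), mir-44 (1 of 3, miR-247; miR-44/miR-45 and miR-61 not), mir-2 (1 of 2, miR-2 by 1.61 on average, from 0.11 in ma192 and -3.33 in ma202; miR-43 not), mir-238/mir-239 (1 of 3, miR-238; miR-239a and miR-239b not) and seam (1 of 2) lists and among the neuron miRNAs (1 of 3, miR-791; lsy-6 and miR-124 not). Falls also came to 2 of 3 in the mir-50/62/90 list, 2 of 3 in the intestine or stress list, both intestine markers, miR-60 and miR-243, and 4 of 6 late larval and adult markers. Neither mir-75/79 (miR-75 0.63, miR-79 0.47) nor mir-46/47 (miR-46 -0.14, miR-47 0.22) nor the mirtron miR-62 (0.12) had a call, whereas with TMM from guides alone both members of these pairs and the mirtron rose. Adjusted over the list alone, the mir-35 count was 1, the mir-44 count 0 and the others as above. Camera tests compare a list with all other strands. In them guides as a class were lower relative to passengers (adjusted p = 1.62e-39, and with an estimated correlation p = 9.06e-05 and 0.000331). Guides and passengers together make up all strands, so this is 1 relative result and does not show that guides fell. The smallest adjusted p of a family was 0.0882.

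Among RNA pulled down with ALG-1, called bound here, passengers rose and many guides fell. The ALG-1-bound passenger of mir-77 rose 360-fold (log2 8.49 ± 0.67, adjusted p = 1.39e-08, edgeR; n = 4 and 3 here and below), miR-67* 283-fold (8.15 ± 0.80), miR-87* 204-fold, miR-85* 181-fold, miR-43* 142-fold, miR-52* 140-fold, miR-64* 131-fold, miR-235* 129-fold and miR-793* 127-fold. No read of miR-255* was seen in the 3 wild-type libraries and 5 to 62 were in the mutants, at least 34.5-fold higher against a floor of 3 counts over the group. Guides with the largest falls were miR-50 (20.0-fold, -4.32 ± 0.40), miR-785, lin-4 (12.5-fold, -3.65 ± 0.36, adjusted p = 8.29e-08), miR-1 (11.8-fold), miR-241, miR-248, miR-784, miR-49, miR-243 and miR-254 (5.45-fold). let-7 fell 3.82-fold (-1.93 ± 0.41), miR-71 4.26-fold and miR-58 1.93-fold, and miR-35 was not past the threshold (0.31). Of 104 guides 7 rose and 49 fell, and of 71 passengers 62 rose and 2 fell. With TMM from guides alone 21 guides rose and 25 fell, with library size 18 and 28, with all reads 10 and 25, and with DESeq2 size factors 6 and 61. Under all 5 scalings 24 guides fell, among them let-7 (-2.35 to -1.23), lin-4 (-4.04 to -2.91), miR-1, miR-50, miR-71, miR-80, miR-82 and miR-241, and 6 rose: miR-36, miR-75 (2.26 to 3.37), miR-79, miR-246, miR-787 and miR-788. Under the same 5, 59 passengers rose and 1 fell.

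The passenger-to-guide ratio among ALG-1-bound reads rose in 57 of 72 hairpins and fell in 0 (limma, 57 at unadjusted p, median 4.68, 25.5-fold, 66 changes above 0). Every hairpin shared 1 variance in that fit, so each change carries a standard error of 0.88. The lin-4 ratio came first (log2 10.21), but lin-4* had 3, 1 and 0 reads in the wild-type libraries, and with an offset of 5 lin-4 stood at 8.12, below mir-87 (8.41) and mir-77 (8.36). It had a passenger share of 0.000939% in wild type, 7.86% ± 2.84 (SD, n = 2) in ma192 and 0.249% ± 0.0197 in ma202. At the offset of 0.5 mir-87 followed (640-fold, 0.438% in wild type, 91.2% ± 1.79 in ma202), then mir-77 (416-fold), mir-67 (401-fold), mir-64, mir-235 (0.191% to 31.1% ± 2.76), mir-86, mir-793, mir-241 and mir-56. let-7 rose by 6.65, mir-58 by 6.60 and mir-71 by 6.13, whereas mir-788 and mir-62 were not past the threshold (-1.32 and -1.18). Across strands the total RNA and ALG-1-bound changes went together (Pearson r 0.828 for 104 guides and 0.890 for 71 passengers, Spearman 0.807 and 0.895), strands not being independent replicates.

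Averaged over both alleles, most bound guides of the let-7 and mir-58 families fell strand by strand and miR-75 and miR-79 rose, each past the threshold in 1 allele only, though no family passed a test of the list as a whole. In the let-7 family 6 of 7 fell and 0 rose (miR-84 by 1.08, miR-48 not past the threshold), in the mir-58 family 4 of 5 fell (miR-80, miR-81, miR-82, miR-58), in the mir-64 family 4 of 5 (miR-66, miR-64 and, with 0.30 in ma202 against -2.72 in ma192, miR-65) and in the mir-72 group 3 of 3 (median -1.68). With TMM from guides alone these became 0 higher and 4 lower, 0 and 2, 1 and 1, and 0 and 2. miR-75 rose 6.28-fold (2.65 ± 0.37, adjusted p = 5.3e-06) and miR-79 2.98-fold as means of the alleles, and both also rose with TMM from guides alone. By allele miR-75 stood at 4.53 in ma202 and 0.77 in ma192, where it was not past the threshold, and miR-79 at 2.21 in ma192 and 0.94 in ma202, where it was not. In the mir-51 family 1 rose and 2 fell, the miR-52 mean standing at 0.76 (adjusted p = 0.0337) from 2.18 in ma192 and -0.66 in ma202, and miR-56 falling by 1.49, and with TMM from guides alone 2 rose and 1 fell. In the mir-35 family 1 rose and 1 fell (1 and 0 adjusted over the list alone, 5 and 0 with TMM from guides alone; median 0.62; miR-42, miR-40 and miR-37 not past the threshold). Of broadly expressed miRNAs 1 rose and 5 fell, of the late larval and adult markers 0 and 4, of the intestine or stress list 1 (miR-246) and 1, of mir-238/mir-239 0 and 2 (miR-238, miR-239a), of mir-50/62/90 0 and 2 (miR-50, miR-90), and of the intestine, seam and lin-4 lists 0 and 1 each. The mir-44, mir-2, mir-46/47 and neuron lists and the mirtron had 0 calls in edgeR. Adjusted over the list alone the other counts were unchanged. In camera passengers were higher as a class (adjusted p = 9.37e-28; 0.00142 for guides and 0.0229 for passengers with an estimated correlation), and the smallest adjusted p of a family was 0.0842.

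In L2 larvae, a stage before mature let-7 normally accumulates, the passenger-to-guide ratio rose in 48 of 72 hairpins and fell in 0 (limma, 49 at unadjusted p, median 4.55, 23.4-fold; n = 3 mutant and 2 wild-type libraries). That fit left 2 residual degrees of freedom, and its hairpins in effect shared 1 variance, as in the immunoprecipitations. Its p values therefore rest on a spread pooled over hairpins, which are not independent replicates. The largest rises were mir-86 (164-fold, log2 7.36 ± 1.69, adjusted p = 0.00105), mir-52 (149-fold), mir-77, mir-64, mir-72, mir-234, mir-84, mir-81, mir-1 and mir-793 (6.13). let-7 rose by 4.76 and lin-4 by 4.11, mir-58 by 5.79, and mir-71 (3.21) and mir-35 (2.95) were not past the threshold. Against the wild-type library of the same number the median ratio change was 4.14 (ma192) and 4.88 (ma202) in replicate 1 and 4.34 (ma202) in replicate 2. In all 3 mutant libraries 60 hairpins lay above both wild-type libraries, against 10% by chance. Without ma202 replicate 1 the count of risen hairpins was 13 and without ma202 replicate 2 it was 15. The libraries of 1 genotype differed: let-7* was 53.6% (Wilson interval 48.95 to 58.19%) of let-7 hairpin reads in ma202 replicate 1 and 2.12% (1.51 to 2.96%) in replicate 2, below wild-type replicate 1 at 5.26% (4.70 to 5.89%), and lin-4* 0.506% and 22.2% of those of lin-4.

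Strand by strand, edgeR called 0 of 175 strands in both alleles of L2 animals, with 50 higher and 11 lower at unadjusted p under 0.05, whereas DESeq2 called 52 passengers higher, 1 passenger lower and 39 guides lower. The edgeR count of 0 depended on the scaling, with 24 calls by library size, 44 with TMM from guides alone, 18 by all reads and 0 with DESeq2 size factors. The L2 libraries also split by replicate number: miR-2 stood at 40551 (wild type) and 86466 CPM (ma202) in replicate 1 and at 526 and 669 in replicate 2, and miR-62 at 16085 and 14969 against 368 and 409. With replicate number as a block, which leaves 1 residual degree of freedom, edgeR called 74 strands in both alleles and 79 in ma202. let-7 was lower without passing (-3.88 ± 1.67, adjusted p = 0.147), as were miR-241 (-3.26 ± 1.07), miR-50 (-2.91), miR-1 (-2.74), miR-84 (-2.38), miR-48 (-2.33 ± 0.83), miR-65 (-2.25) and lin-4 (-1.55). miR-58 (-0.10), miR-71 (0.13), miR-35 (0.21), miR-52 (0.48), miR-80 (-0.72) and miR-2 (1.36) were not past the threshold either. Left out in turn, WT replicate 1 gave 48 calls, WT replicate 2 gave 11, the ma192 library 9, ma202 replicate 1 gave 4 and ma202 replicate 2 gave 2. For ma202 alone edgeR called 10 strands, all passengers: miR-234* (176-fold), miR-86* (93.4-fold), miR-67*, miR-58* (87.1-fold), miR-79*, miR-42*, miR-2*, miR-90*, miR-1* and miR-55*, each with an adjusted p of 0.0424 and named after their values were seen. That count was 38 by library size, 47 with TMM from guides alone, 6 with DESeq2 size factors and 77 in the DESeq2 Wald test. Without ma202 replicate 1 there were 0, without WT replicate 1 46 and without WT replicate 2 16. No family list had a call in either contrast over all strands. Adjusted over the list alone, 3 late larval and adult guides and both seam guides were lower in both alleles. In camera the let-7 family (adjusted p = 0.00111), the late larval and adult markers (0.00359) and the broadly expressed miRNAs (0.0179) were lower relative to other strands, each 0.601 with an estimated correlation; with TMM from guides alone their medians were -1.77, -1.70 and -0.75. Guides as a class were lower relative to passengers, again 1 relative result (camera, adjusted p = 3.24e-39, and 0.0158 and 0.0168 with an estimated correlation). Mixed-stage and L2 changes had a Pearson r of 0.508 across 104 guides and 0.681 across 71 passengers (Spearman 0.474 and 0.671).

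The alleles differed from each other in named passengers. In mixed-stage total RNA miR-44/miR-45* was 90.5-fold higher in ma202 than in ma192 (adjusted p = 4.47e-06, edgeR, n = 2 each), miR-60* 36.6-fold, miR-41* 32.3-fold and miR-86* 9.39-fold higher, and miR-243* was 31.1-fold lower, miR-80* 18.3-fold lower, lin-4* 16.2-fold lower and miR-56* lower by 3.52 on the log2 scale. Among guides miR-75 was 5.92-fold higher, and miR-244, miR-786, miR-2 and miR-50 were lower. These strands, and those of the next sentence, were chosen after their values were seen. Among ALG-1-bound reads miR-44/miR-45* was 223-fold higher in ma202, miR-60* 33.3-fold and miR-75 13.6-fold, while miR-80* was 43.2-fold lower, lin-4* 22.8-fold and miR-52 7.17-fold lower. In the ratio test mir-44/mir-45 was higher in ma202 by 5.85 ± 0.95 (limma, adjusted p = 0.000573), mir-80 lower by 5.65 on the log2 scale (adjusted p = 0.00019) and lin-4 lower by 3.36 (adjusted p = 0.0105), with 13 hairpins higher and 2 lower in total RNA and 15 and 3 in the immunoprecipitations. The mir-80 passenger share was 14.5% ± 1.33 (SD, n = 2) in ma192, 0.337% ± 0.0349 in ma202 and 0.196% in wild type, and that of mir-44/mir-45 was 3.23% ± 1.53, 63.4% ± 17.6 and 4.81% ± 4.69. L2 animals did not show the mir-80 difference, with 26.5% in ma192, 26.5% and 11.8% in ma202 and 1.94% in wild type, and their lin-4 shares were 2.61% in ma192 against 0.506% and 22.2% in ma202.

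Over all strands edgeR called 20 higher and 25 lower in ma202 than in ma192 in mixed-stage total RNA, and 36 and 27 in the immunoprecipitations. Guides made 7 of the higher and 18 of the lower calls in total RNA and passengers 13 and 7; with TMM from guides alone these were 11 and 7 guides and 25 and 5 passengers. Bound guides made 14 and 21 of the calls and passengers 22 and 6, against 17 and 9 guides and 23 and 5 passengers with TMM from guides alone. With replicate number as a block the total RNA count of 45 became 92. It was 12 without ma192 replicate 2, 15 without ma202 replicate 1 and 21 without ma192 replicate 1, and the immunoprecipitation count of 63 was 28 without ma192 replicate 2. By list in total RNA, all 3 mir-72 guides were lower in ma202 (median -2.00), as were 3 of the mir-51 family (4 adjusted over the list alone, median -1.36) and 2 of mir-50/62/90, while the median of all strands moved from -0.12 to 0.42 with TMM from guides alone. Among bound guides 5 of 6 in the mir-51 family were lower, and in the mir-58 family 3 were higher and 2 lower. In camera guides as a class were lower relative to passengers (adjusted p = 0.00234 in total RNA, 0.00703 bound). Neither class kept this with an estimated correlation (0.0545 and 0.109, 0.244 and 0.497). Against wild type, ma192 had 59 strands higher and 45 lower in total RNA (62 and 33 bound) and ma202 had 62 and 62 (67 and 46 bound), with the wild-type libraries shared. Guides made 3 and 44 of the ma192 calls and 3 and 59 of the ma202 calls in total RNA, against 15 and 15, and 14 and 11, with TMM from guides alone.

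In wild-type animals the immunoprecipitation itself held fewer passengers than total RNA, the background against which bound passengers in the mutants stand. The bound level of lin-4* was 26.9-fold below that in total RNA (log2 -4.75), miR-87* 19.8-fold, and miR-41*, miR-38*, miR-72*, miR-62*, miR-55*, miR-77*, miR-52* and miR-71* were lower by 4.15 to 1.69 on the log2 scale. Bound guides with higher levels were miR-791 (7.89-fold, 2.98 ± 0.53, adjusted p = 0.000269, edgeR, n = 3 each), miR-90 (5.26-fold), miR-235 (4.95-fold) and miR-252 (3.92-fold), and those with lower levels were miR-789, miR-1829a, miR-41 and miR-77. These strands were chosen after their values were seen. In total 30 of 72 passengers were lower and 0 higher, and 4 of 104 guides were higher and 4 lower. By list 1 mir-35 guide was lower (0 adjusted over the list alone), 1 broadly expressed guide lower, and 1 guide each of mir-50/62/90 (miR-90) and the neuron list (miR-791) higher. The count of 38 strands was 21 without wild-type immunoprecipitation replicate 2. In camera passengers were lower as a class than guides (adjusted p = 1.82e-14; 0.0181 for passengers with an estimated correlation).

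Whether binding to ALG-1 changed in the mutants was asked with the interaction of genotype and immunoprecipitation. Bound over total, miR-87* rose by 4.09 ± 0.83 more in the mutants than in wild type (adjusted p = 0.00466, edgeR), miR-77* by 3.49, miR-51* and miR-72* by 2.94, miR-238* by 2.89 and miR-67* by 2.58. Among guides miR-787, miR-75, miR-52 (2.37 ± 0.43, 5.15-fold, adjusted p = 0.00183), miR-246, miR-54, miR-55, miR-60, miR-65, miR-56, miR-77, miR-51 and miR-64 rose in the same contrast, by 2.60 to 1.57. let-7 (0.13), lin-4 (-0.54), miR-58 (0.46), miR-71 (0.33), miR-1 (-0.11) and miR-35 (1.23) were not past the threshold. In all 18 strands rose (12 guides, 6 passengers) and 0 fell, with 41 and 1 at unadjusted p and 4 calls in DESeq2. By list these were 5 of 6 mir-51 guides (6 adjusted over the list alone), 2 mir-64 guides, 3 broadly expressed, 1 of mir-75/79, 2 of the intestine or stress list, 1 intestine marker and, adjusted over the list alone, 1 of mir-238/mir-239. The median over all strands was 0.93 in this scaling and 0.09 with TMM from guides alone, which called 0 strands, and library size called 0 and all reads 2, so no strand passed under all 5 scalings; the mir-51 median was 1.81 and 0.96 in the first and the second of these. The count was 2 without ma192 immunoprecipitation replicate 1, 9 without wild-type immunoprecipitation replicate 2, 11 without ma192 total RNA replicate 2 and 31 with replicate number as a block. camera placed the mir-51 family above other strands (adjusted p = 0.00653, 0.879 with an estimated correlation). The passenger-to-guide ratio had 0 of 72 hairpins past the threshold in this interaction (limma, 5 at unadjusted p, median -0.22, mir-87 first at 3.64 with adjusted p = 0.136), 1 with the block and 1 without ma192 immunoprecipitation replicate 2.

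The 3′ ends of guide strands also differed. An added U here is any run of U past the end of the listed sequence. That sequence was not the most abundant form of every guide, for example not of miR-90. Guides ending in an added U (templated or not, since no genome was used) made up 3.13% ± 0.160 (SD, n = 3) of guide reads in wild-type mixed-stage total RNA and 6.52% ± 0.281 (SD, n = 4) in the mutants, averaged over strands. The share went from 3.35% ± 0.174 to 9.74% ± 1.04 among ALG-1-bound reads and from 2.95% ± 0.223 (n = 2) to 6.31% ± 0.519 (n = 3) in L2 animals. Bound miR-59 carried the added U on 5.79% of reads in wild type and 53.1% ± 7.09 in the mutants, miR-255 on 3.99% and 48.8%, and miR-58 on 1.59% and 10.4%. In total RNA the share went from 5.21% to 13.9% for let-7, from 3.77% ± 0.525 to 20.2% ± 10.1 for miR-64 and from 11.5% ± 0.354 to 29.6% ± 5.19 for miR-62, guides named after their values were seen except let-7, miR-58, miR-62 and miR-64. Every mutant library lay above every wild-type library for 48 of 97 guides in total RNA, 67 of 97 in the immunoprecipitations and 50 of 93 in L2 animals, and below for 2, 1 and 0, where chance gives 2.86%, 2.86% and 10% each way. The exact permutation p of the mean was 0.0286, 0.0286 and 0.1, and adjusted over the 10 end and length measures 0.0952, 0.143 and 0.333.

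**Figure D3:**
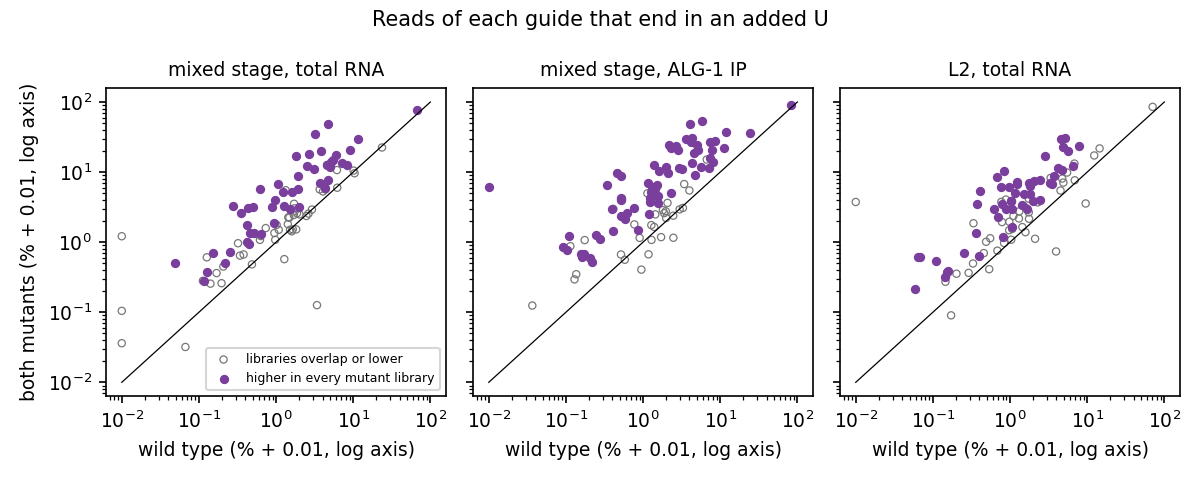
Percentage of reads of each guide with an added 3′ U, mean of the mutant libraries (vertical axis) over mean of the wild-type libraries (horizontal axis), both log axes with 0.01 added, a point for each guide and a panel for each library set, with a line of equal values. Filled points, 48, 67 and 50 guides in the 3 panels, lay higher in every mutant library than in any wild-type library.

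Other classes of small RNA were compared as shares of all reads. The measured miRNAs made up 54.2% ± 2.03 (SD, n = 3) of reads in wild-type mixed-stage total RNA and 35.5% ± 6.11 (SD, n = 4) in the mutants (exact permutation p = 0.0286, 0.171 adjusted over 6 classes). Reads of 17 to 18 nt, measured after the data were seen, made up 6.32% ± 4.88 (SD, n = 3; 2.92 to 11.9%) in wild type and 14.01% ± 2.87 (SD, n = 4; 10.96 to 17.7%) in the mutants of that set (exact permutation p = 0.0571). Reads of 21 nt that start with U, the form of the germline piRNAs called 21U-RNAs, made up 6.78% in wild type and 10.5% in the mutants of that set (exact p = 0.257), and 4.90% and 2.73% in the immunoprecipitations (exact p = 0.0286, 0.171 adjusted). Reads of 22 nt that start with G, the form of secondary siRNAs, made up 1.87% and 2.21% of mixed-stage total RNA (exact p = 0.743), and those of 26 nt that start with G, the form of 26G-RNAs, 0.287% and 0.678% (exact p = 0.0857). In the immunoprecipitations and in L2 animals the miRNA shares of 61.3% and 63.9% in wild type and 58.9% and 57.0% in the mutants differed by less than the spread between replicates; the L2 shares include the 10.4% of reads over 30 nt in ma202 replicate 2.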

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

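The tests of run or preparation, shared reads, abundant hairpins, scaling, carry-over and preparation weighed here were chosen only after the result was seen, whereas the counts over other splits of the samples were planned, except that the splits of the interaction were changed after their result was seen.

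Passenger strands were higher against their guides in mutant libraries of all 3 sets. A shared run or preparation marked by replicate number is argued against by the mutant libraries themselves, which exceeded the wild-type library of the same number by a median of at least 3.42 (log2) in all 11 such pairs. Reads shared between near-identical strands are argued against by the 54 hairpins with no such relative, whose median was 4.75 with 47 past the threshold, and a few dominant hairpins by the 62 left without the 10 most abundant, at 4.48 with 49 past it. A change in strand retention by the mutant Argonaute may underlie the pattern, as a hypothesis found and tested on the same data, while a make-up difference between whole animals stays open and untested.

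In 35 splits of the 7 libraries, the real one alone gave as many strands in mixed-stage total RNA (1 of 35, 130 against 12 at most in another), as many hairpins (1 of 35, 60 against 30), as many bound strands (1 of 35, 120 against 43) and as many bound hairpins (1 of 35, 57 against 45). A share of 1 in 35 is the smallest that these splits allow. The other splits mix genotypes inside their groups, which can lower their counts, so these ranks alone do not exclude chance. The next highest split in each put ma192 replicate 2 with wild type. Among the 9 splits matched on replicate numbers the next highest gave 0, and 9 are too few for a share under 0.05.

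Guide strands were lower in mutant libraries under the scaling over all strands (median -1.35 in mixed-stage total RNA). Rising passengers that shift the scaling factors and fill the libraries are consistent with the median of -0.23 under library size alone, so most of the common fall may come from scaling. Scaled to all reads the median was -0.77, lower than passengers filling the miRNA reads can give, so that explanation is argued against for this scaling. More reads of other small RNAs, lowering every guide alike, cannot be told apart from fewer miRNAs: the highest miRNA share of a mutant library was 42.4%, below the lowest wild-type share of 52.3%, reads of 17 to 18 nt, a possible sign of RNA breakdown, averaged 14.01% against 6.32% with overlapping libraries, and shares alone do not say which class changed. Neither makes guides differ from each other, and 17 guides, lin-4, miR-1 and miR-50 among them, were lower under all 5 scalings. miR-36 and miR-41, of the embryonic mir-35 family, were higher under all 5. A make-up difference between whole animals, such as in stage, could make guides differ, and it stays open and untested here too.

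The passenger share was lower in replicate 2 than in replicate 1 of the mutant immunoprecipitations, at 0.340 of it in ma192 and 0.393 in ma202. Carry-over of unbound total RNA in replicate 1 is argued against for ma202 by 3 classes of other small RNA and 2 unnamed sequences, recovered at 0.309 at most of their level in total RNA per miRNA read, against 0.920 for passengers. For ma192 carry-over cannot be told apart from other causes: 22G-like reads were recovered at 0.825, 26G-like at 0.487, 21U-like at 0.168 and the unnamed sequences at 0.0536 and 0.0665, against 0.914 for passengers, and all 5 were higher than in replicate 2. In wild type 22G-like recovery was 0.866, 0.124 and 0.391 in replicates 1 to 3, with passengers at 0.610, 0.446 and 0.567. There 21U-like recovery was 0.444, 0.498 and 1.098, and 26G-like recovery 0.336, 0.0779 and 1.164. Per miRNA read these last 2 classes were thus not depleted in wild-type replicate 3, where the unnamed sequences stood at 0.0297 and 0.0368. A high 22G-like recovery was thus not particular to ma192. A preparation difference acting alike on every genotype is argued against by the wild-type shares, where replicate 2 stood at 0.909 of replicate 1. Taken over total RNA, however, passengers fell in wild type too, from 0.610 to 0.446, so a part acting alike is not excluded. On that measure ma192 fell from 0.914 to 0.298 and ma202 from 0.920 to 0.374. A difference in the mutant animals or in their immunoprecipitation between replicates stays open and was not tested.

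Tests of the difference between groups put 45 strands (mixed-stage total RNA) and 63 strands (bound) apart between ma202 and ma192, and 15 and 18 hairpins in their passenger-to-guide ratio, miR-44/miR-45*, miR-80* and lin-4* first among them. The total RNA count was 12 without ma192 replicate 2, 15 without ma202 replicate 1 and 21 without ma192 replicate 1, and the bound count 28 without ma192 replicate 2. The interaction of genotype and immunoprecipitation called 18 strands, miR-87* and miR-52 among them, and was 2 without ma192 immunoprecipitation replicate 1, 9 without wild-type immunoprecipitation replicate 2 and 11 without ma192 total RNA replicate 2. It was 0 by library size and with TMM from guides alone and 2 by all reads and with DESeq2 size factors, so no strand passed under all 5 scalings.

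The splits of the interaction were counted in 3 ways. The planned one regrouped total RNA and immunoprecipitations independently, and 5 of 100, the real one included, gave 18 strands or more (highest other 116), but unequal regrouping lets the genotype effect into the contrast. Splits made alike in both gave 1 of 35 (highest other 0), but leave that effect inside the groups, which can lower the counts of the others, so neither decides for the 18. With a block for each pair of total RNA and immunoprecipitation, which takes the effect out, 1 of 35 splits gave 31 strands, the real one, the highest other being 7. That is the smallest share that 35 splits allow. The test was changed after its result was seen, so it does not exclude chance for the blocked count. Only 9 of these splits are matched on replicate numbers, too few for a share under 0.05, and the blocked count was not tried under other scalings. In the ratio interaction, which called 0 hairpins without the block, 2 of 35 blocked splits gave as many as the real one (1, highest other 6), so chance is not excluded.

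For immunoprecipitation against total RNA in wild type, 1 of 10 splits gave 38 strands, the real one, the highest other being 0, and 10 splits are too few for a share under 0.05.

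Of 36 sets of 4 libraries checked for a library far from the others, 1 stood out: guides with longer 3′ ends made up 9.53% in ma202 mixed-stage total RNA replicate 1, and chance gives about 1 in 20 groups.

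Reads longer than 30 nt, which no strand count used but which count among all reads in the class shares and the scaling to all reads, made up 10.4% of the ma202 L2 replicate 2 library against 0.358% in wild-type L2 replicate 2. Reads of another organism made up 0.844% and 1.38% of the ma192 immunoprecipitations and 0.846% and 1.59% of those of ma202, against 0.555% in the highest wild-type one. A sequence without a name in the sources used here reached 56997 and 11062 CPM in the ma192 mixed-stage total RNA libraries, 49391 and 23755 in those of ma202 and 33377, 17962 and 2021 in wild type. Another reached 24784 and 9003, 6794 and 3284, and 10132, 6557 and 4445.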

How the results depend on the processing

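limma without robust moderation was tried only after the data were seen, and all other alternatives were planned. In mixed-stage total RNA 61 passenger rises and the falls of lin-4, miR-1 and miR-50 kept their side under all 5 scalings. Of the values of named strands under the alternatives 3434 had the call of the main result and 231 the same direction but no longer past the threshold. Another 99 were newly past it and 16 counted as opposite in sign. For named hairpins these were 607, 17, 2 and 0. A change of sign counted as opposite only where the main or the alternative value passed the threshold. Any other change of sign is among the 3434 and 607.

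The 16 values counted as opposite all concern guides in mixed-stage total RNA. With TMM from guides alone miR-58 stood at 0.35, miR-84 at 0.17, miR-237 at 1.202, miR-42 at 1.26, miR-52 at 0.13, miR-77 at 0.020, miR-72 at 0.23, miR-74 at 0.062, miR-46 at 1.27, miR-90 at 0.23 and miR-239a at 1.13. With library size only miR-58 stood at 0.095, miR-42 at 1.05, miR-72 at 0.038, miR-46 at 1.05 and miR-90 at 0.018. These scalings move all strands of a contrast together, and they moved the median of all strands from -0.25 to 1.14 and 0.88.

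Alternatives moved several counts, and the cause was not tested. With the replicate block the ma202 against ma192 count in mixed-stage total RNA was 92, L2 ma202 79, L2 both alleles 74 (only 2 pairs of L2 libraries share a number, and their residuals mirror each other, so r 0.754 is a single value), the interaction 31 and its ratio test 1, and no other count moved beyond 1.5 times. DESeq2 size factors gave 6 (L2 ma202) and 2 (interaction), library size 38 (L2 ma202), 24 (L2 both) and 0 (interaction), and TMM from guides alone 47, 44 and 0. The DESeq2 Wald test gave 77 (L2 ma202), 92 (L2 both) and 4 (interaction), no filter on low counts 7 (L2 both), and all reads 18 (L2 both) and 2 (interaction). Switches by the mean of the mutant libraries numbered 6 in mixed-stage total RNA, 3 bound and 4 in L2 animals. With an estimated correlation camera called 0 families in each of mixed-stage ma192, L2 ma202, L2 both alleles and the interaction, and the adjusted p of the ma202 against ma192 classes became 0.0545 and 0.109 (guides and passengers, total RNA), 0.244 and 0.497 (bound) and that of bound ma192 passengers 0.0526.

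With each library left out in turn, counts ranged over 12–52 (ma202 against ma192, mixed-stage total RNA), 28–63 (the same, bound), 0–46 (L2 ma202), 2–48 (L2 both), 21–47 (immunoprecipitation against total RNA), 2–20 (interaction), 13–47 (L2 ratio) and 0–1 (ratio interaction). They ranged over 108–131 and 105–123 for both alleles in mixed-stage total RNA and bound, 76–107 and 70–99 for ma192, 103–125 and 95–114 for ma202, and 59–64 and 53–58 for the ratios. The passenger share difference ranged over 11.2–13.2 in mixed-stage total RNA (exact p 0.0667 to 0.1, with fewer samples), 5.58–9.41 bound and 24.9–30.3 in L2 animals. A lone library left in a group was assumed to vary like the others.

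Depth limits passengers with few wild-type reads, such as lin-4*, which held 0.000939% of bound lin-4 reads, and miR-255*, with 0 bound reads.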

Other observations

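Hairpins differed in how far their passenger rose, and 3 hypotheses on this were tested across the 72 hairpins of mixed-stage total RNA, each with 100000 permutations and adjusted over the 3; the test on wild-type L2 shares was chosen only after the result was seen.

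Hairpins whose passenger already held a larger share in wild-type L2 animals, such as mir-791 (25.6%), mir-46 (22.5%) and mir-36 (16.9%), changed less, and those with a small share, such as lin-4 (0.228%) and mir-81 (0.196%), changed more, these hairpins being named after their values were seen: the change in ratio had a Spearman rho of -0.665 with the wild-type L2 passenger percentage (95% interval -0.798 to -0.490, Pearson r -0.557, permutation p = 1e-05, the smallest possible, adjusted 3e-05). The L2 libraries took no part in the mixed-stage ratio, but a wild-type share that is alike in both sets would by itself favour a negative rho. Hairpins of a family are not independent, so the p values and intervals here and below may overstate the evidence. The negative rho could come from a strand choice that the mutants loosen most where wild type is strictest. A low starting share also leaves more room for a rise, which the test does not separate.

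Hairpins with a more stable duplex were predicted to keep more passenger. The change instead had a rho of 0.285 with the duplex energy (95% interval 0.0791 to 0.488, Pearson r 0.325, permutation p = 0.0160, adjusted 0.0241), so the less stable duplexes changed more and the prediction failed.

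Passengers that start with U, the first base that worm Argonautes of this kind are known to favour, were predicted to change more. The 13 passengers with U had a mean change of 4.21 and the others 4.41, a difference of -0.21 (95% interval -1.53 to 1.09, permutation p = 0.788), too wide to tell.

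Passenger reads started at the exact 5′ end more often in the mutants of mixed-stage total RNA (95.3%) than in wild type (92.2%), with an exact permutation p of 0.0286, adjusted 0.0952. In the immunoprecipitations (94.5% against 93.2%, exact p = 0.171) the libraries overlapped, in L2 animals the shares were 95.2% and 92.6% (exact p = 0.2), and guides of mixed-stage total RNA went the other way, 96.1% against 96.8% (exact p = 0.0571). Guides with longer 3′ ends went from 6.17% ± 0.597 (SD, n = 3) to 9.18% ± 0.228 (SD, n = 4) there, from 6.75% to 13.3% bound and from 5.87% to 9.21% in L2 animals. miR-90 carried U past its listed end on 67.9% of reads in wild-type and 77.0% in mutant mixed-stage total RNA. The listed sequence of miR-90 was only number 2 among its forms by reads, so that U may belong to its usual end. miR-795 carried an added U on 4.58% of reads in wild-type and 29.2% in mutant L2 animals. Both guides were named after their values were seen.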
